A study of Mus musculus with 4 samples.

How the data were processed

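CUT&Tag with an antibody against Ruvbl2 was carried out on 2 HSC and 2 LSC libraries from mouse bone marrow. Per the labels' protocols, each library started from 2000 to 5000 sorted cells and was amplified over 17 to 20 PCR cycles with a commercial CUT&Tag kit. The labels name a goat anti-rabbit IgG as the secondary antibody and do not give the host of the Ruvbl2 antibody. Its catalogue number ends in -Ig, a suffix the supplier gives to mouse monoclonals, which an anti-rabbit antibody would bind poorly, so how far the signal depends on the Ruvbl2 antibody is open. No IgG or other control library is named in the labels. Groups and replicate numbers were taken from the sample titles, because the cell type label reads haematopoietic stem cell for all 4 libraries, the LSC libraries included. Peak names in the files follow a naming scheme shared by replicate 1 of both groups and another shared by replicate 2.

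Per the submitters' processing notes, reads were checked with FastQC 0.11.5 and aligned with Bowtie2 2.2.9, peaks were called with MACS2, ChIPseeker was used, and the genome build was mm10. Versions of MACS2 and ChIPseeker, the calling threshold, read filters and the handling of duplicate reads are not given in the sources used here. Each library had a peak list of its own, so peaks were called per library and not on pooled samples. The deposited score is 10 times the −log10 q-value cut to a whole number. The deposited fold is MACS2's ratio of the pileup at the summit to the background of the same library, and the deposited −log10 p and −log10 q values test that pileup against that background. All deposited peaks had a −log10 q of at least 5.07. From fold and −log10 p together, a whole-number pileup (within 0.05) over a single background per library was recovered for 100% of the peaks tested, so ranking by fold or by p gives the same order and no local background was used. Fold, score, p and q were treated as the peak's own value and served to rank or filter peaks within a library.

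Peaks on chromosomes 1 to 19, X and Y were kept, records with the same start and end were collapsed to the strongest, and the 20000 peaks with the largest −log10 p were taken from each library so that lists had equal lengths. The weakest listed peak had a fold of 22.7 in HSC replicate 1, 12.7 in HSC replicate 2, 28.4 in LSC replicate 1 and 18.2 in LSC replicate 2. Overlap meant at least 1 bp. Gene coordinates came from a RefSeq table of the assembly GRCm38.p6, which has the coordinates of mm10. It holds gene starts and ends without strand, exons or transcripts. The promoter windows planned before the data were examined were therefore replaced by windows of 1000 bp on each side of both ends of each of 21887 protein-coding genes, so a start site and a 3′ end are not told apart, and peaks were divided into gene end, gene body and intergenic. These windows covered 2.91% of the genome length used.

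A gene or region was LSC-only when listed in both LSC and in neither HSC library, and HSC-only in the reverse case; the strict form also required no peak of any strength in the other group, for a gene in its end windows. Counts were set beside those of the other splits of the 4 libraries into pairs. Chance was estimated from 100 circular shifts of each list along its chromosomes (10 for the full lists, 20 per pair of libraries; seeds fixed). Repetition of the cell type difference at both replicate numbers was tested with a two-sided Fisher's exact test over genes or regions, an addition to the planned tests. For 21 gene lists fixed before the data were examined, a two-sided Fisher's exact test compared LSC-only with HSC-only genes, adjusted by the Benjamini-Hochberg method at 0.05, and the test of genes listed in all 4 libraries was added after the data were seen. In the lists, 2 nucleoporin genes were matched by a synonym and 1 erythroid gene had no match. The named genes were a fixed set of 13 from the series' subject, the 15 strict genes per direction with the best worse-of-2 rank, the 10 genes in all 4 libraries with the best worst rank, and up to 4 members per list and direction that were LSC-only or HSC-only; predicted genes were passed over. Named regions were the 5 strongest strict ones per direction.

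On simulated lists with 100 LSC-only, 100 HSC-only and 600 common genes planted among 21887 genes, 94.0% of the LSC-only, 94.0% of the HSC-only and 100% of the common genes were recovered. By chance 19 LSC-only, 28 HSC-only and 0 common calls were made, and of 18 random lists 0 passed either test. Every planted gene had a peak in each library of its group, so high recovery was built in. The simulation checks the procedure. It does not estimate recovery or chance calls in the real libraries, where 89.5% of regions were found in a single library. Alternatives were the full lists, the 10000 and 40000 strongest peaks, ranking by fold, overlap of at least 50%, summit windows of 200 bp, gene-end windows of 3000 bp, the summit in place of the whole peak, autosomes alone, a replicate block and leaving out each library. Those added after the data were seen were a −log10 q of at least 20, peaks at least 2 times as long as the library's shortest, and the replicate 2 libraries alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Peaks on the mitochondrial genome and on unplaced or patch sequences entered no comparison. The individual genes behind the B cell counts are not reported here.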

Results

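Chromatin was profiled with a Ruvbl2 antibody by CUT&Tag, in which an antibody directs a transposase to chromatin, in 2 kinds of mouse bone marrow cell. Ruvbl2 is an AAA+ ATPase that, with its partner Ruvbl1, is part of the INO80, SRCAP and TIP60/p400 chromatin complexes and of the R2TP co-chaperone. Haematopoietic stem cells (HSC, sorted as CD48-negative, CD150-positive LSK cells) came from mice with 1 floxed allele of Nup214, and leukaemia stem cells (LSC) came from mice of that genotype with leukaemia driven by the MLL-AF9 fusion. The LSC gate, Lin-negative, Sca-1-negative, c-Kit-positive, CD16/32-positive and CD34-positive, also describes granulocyte-monocyte progenitors, so the groups differed in maturation as well as in leukaemia. Each group had 2 libraries, and the labels do not say whether they came from separate animals. Y chromosome peaks numbered 91.8 and 94.2 per 10000 in replicate 1 of HSC and LSC, and 0.561 and 1.24 in replicate 2. The X chromosome held 2.79% and 2.65% of peaks in replicate 1 and 4.27% and 3.94% in replicate 2. These values argue against the same animal as the source of both libraries of a group. The spread between them may thus hold differences between animals as well as technical ones. The deposited lists held 161655 peaks for HSC replicate 1, 286107 for HSC replicate 2, 216077 for LSC replicate 1 and 210541 for LSC replicate 2. Read totals are not in the lists, so sequencing depth is unknown. The background pileup recovered from the peak values, a relative measure of depth and fragment length, was 2.66, 4.34, 4.46 and 3.72 in that order. Comparisons used the 20000 strongest peaks of each library, called listed peaks below, and a gene was listed when such a peak lay within 1000 bp of either of its annotated ends.

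The first question was where the peaks lay and which genes carried them in both cell types. Peaks were concentrated at gene ends in every library, and 636 of 21887 protein-coding genes (2.91%) were listed in all 4 libraries. By worst rank, the strongest common sites lay at Wls, which encodes a Wnt secretion factor, at the shared end of Fbrs and Prr14, at the shared end of the translation factor gene Eif4a1 and the SUMO protease gene Senp3, and at Eif5a, Zfp143, Hdlbp and the shared end of Fam72a and Srgap2. The authors' fold enrichment, a value of each peak within its own library, was 145, 107, 170 and 144 at Fbrs and Prr14 (chromosome 7, positions 127477632 to 127478873 of mm10 in HSC replicate 1) in HSC replicates 1 and 2 and LSC replicates 1 and 2. At Eif5a (chromosome 11, gene 69916712 to 69921958) it was 96.5, 122, 202 and 189. The Wls peak (chromosome 3, 159939405 to 159939690 in HSC replicate 1) stood far above these, with folds of 8810, 5881, 21521 and 7876, and lay just beyond the gene's annotated end at 159938666. The mitochondrial peak had folds of a like size, 3734 to 15130. Regions prone to artefact signal were not filtered out here, so the Wls peak is not shown to be a Ruvbl2 site. Independent lists of the same sizes would share 16.2 genes, 39.2 times fewer, and 100 circular shifts of the peaks along their chromosomes gave at most 1 gene in all 4 libraries. Because adjacent genes can share a peak, the 636 genes rested on 523 distinct sets of peaks. The count was 391 with the 10000 strongest peaks and 3413 with the full lists, and it rose to 1253 without HSC replicate 1 and to 1229 without LSC replicate 1.

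Several gene groups stood out among the genes listed in all 4 libraries, and their members below were chosen after their values were seen. Replication-dependent histone genes led: 21 of 63 (33.3%) were listed in all 4 libraries, among them H1f2, H3c6, H2ac7 and H4c3 on chromosome 13 and H2ac19 with H3c15 on chromosome 3. Of the immediate early genes, which respond rapidly to growth factors and stress, 4 of 18 (22.2%) were listed in all 4, namely Zfp36, Ier3, Egr1 and Fos. Genes for subunits of Ruvbl2's own chromatin complexes followed with 6 of 33 (18.2%): Brd8, Actl6a, Yy1, Ino80, Ep400 and Srcap. Odds ratios against all other protein-coding genes were 17.2 (95% interval 9.63 to 29.97) for the histones, 9.60 (2.29 to 30.7) for the immediate early genes and 7.48 (2.52 to 18.6) for the chromatin complexes. The Benjamini-Hochberg adjusted p over 21 lists, from a two-sided Fisher's exact test, was 7.16e-16, 0.00656 and 0.00233. Olfactory receptor genes, silent in blood cells, were listed in all 4 libraries in 0 of 1106 cases (adjusted p = 4.83e-14 by the same exact test), and vomeronasal receptors in 1 of 353 (Vmn2r2, adjusted p = 0.00323). Oxidative phosphorylation genes, with 6 of 74 including Ndufa11, Ndufs8 and Cox8a, did not pass (adjusted p = 0.0720, Fisher's exact test), but passed under other settings, among them the full lists (adjusted p = 7.39e-07) and the summit in the window (adjusted p = 0.0303). The call for the chromatin complexes was lost among peaks at least 2 times as long as the library's shortest (3 genes, adjusted p = 0.153, Fisher's exact test). That for the vomeronasal receptors was lost with the 10000 strongest peaks (adjusted p = 0.0997, the same exact test). With the full lists the odds ratio of the chromatin complex genes was 4.00. Those of iron handling (4.59), oxidative phosphorylation (3.71) and ribosomal protein genes (3.56) lay near it. At that setting the excess was thus not particular to genes of Ruvbl2's own complexes. The units of these tests were genes, not animals, and neighbouring histone genes such as H2ac11 and H2bc11 shared peaks, so the p-values are too small for the histones. No control library without the Ruvbl2 antibody was used here. The protocol names an anti-rabbit secondary while the antibody's catalogue suffix is one its supplier gives to mouse monoclonals, so the peaks are not shown to depend on Ruvbl2.

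The series title points to ferroptosis, iron and nucleoporin genes. In all 4 libraries, listed peaks lay at Nfe2l2, which encodes the transcription factor of the antioxidant response, at Gsr (glutathione reductase), at Vdac2 (a mitochondrial channel), and at the iron genes Pcbp2 and Ftl1. These made up 2 of 27 ferroptosis defence, 1 of 27 ferroptosis promotion and 2 of 24 iron handling genes, beside 0 of 30 nucleoporin genes. None of these lists passed the all-4 test. With the full lists, iron handling (adjusted p = 0.00105, Fisher's exact test) and ferroptosis defence genes (adjusted p = 0.0486, the same exact test) passed. That setting passed 12 of the 21 lists, so this was not particular to iron or ferroptosis. Ribosomal protein (adjusted p = 7.21e-07) and myeloid genes (adjusted p = 0.000717, Fisher's exact test) were among them. Among the 27 ferroptosis defence genes, 4 were listed in HSC replicate 1, 11 in HSC replicate 2, 4 in LSC replicate 1 and 10 in LSC replicate 2. The genes that promote ferroptosis or make polyunsaturated lipids numbered 5, 9, 2 and 13 of 27 in that order, and iron handling genes 7, 12, 3 and 11 of 24. Nucleoporin genes were listed in 5, 17, 5 and 16 of 30 cases. None of these 4 lists held a gene listed in both libraries of 1 cell type alone, where chance would place 0.209 to 0.280 per list and direction. Nup214 itself carried a listed peak in HSC replicate 2 (rank 4157), LSC replicate 1 (rank 3430) and LSC replicate 2 (rank 1007), and no peak of any strength at its ends in HSC replicate 1. In LSC replicate 1 that peak lay at the opposite end of the gene (chromosome 2, 32054548 to 32054819) from the peaks of both replicate 2 libraries. Ruvbl2 carried a listed peak in both HSC libraries and LSC replicate 2, with folds of 37.7, 38.9 and 52.1, and none in LSC replicate 1. Ruvbl1 was listed in no library, but had peaks below the cut in HSC replicate 2 (rank 21212) and LSC replicate 2 (rank 63251). Gpx4, which reduces lipid peroxides, was listed in LSC replicate 2 alone, Slc7a11 (the cystine transporter) and Acsl4 (which activates polyunsaturated fatty acids) in HSC replicate 1 alone, Tfrc (the transferrin receptor) in LSC replicate 2 alone and Fth1 (ferritin heavy chain) in HSC replicate 2 alone. Peaks too weak to be listed lay at Gpx4 and Fth1 in every other library. Such peaks also lay at Acsl4 in both replicate 2 libraries, at Tfrc in HSC replicate 2 and LSC replicate 1, and at Slc7a11 in LSC replicate 2.

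**Figure D1:**
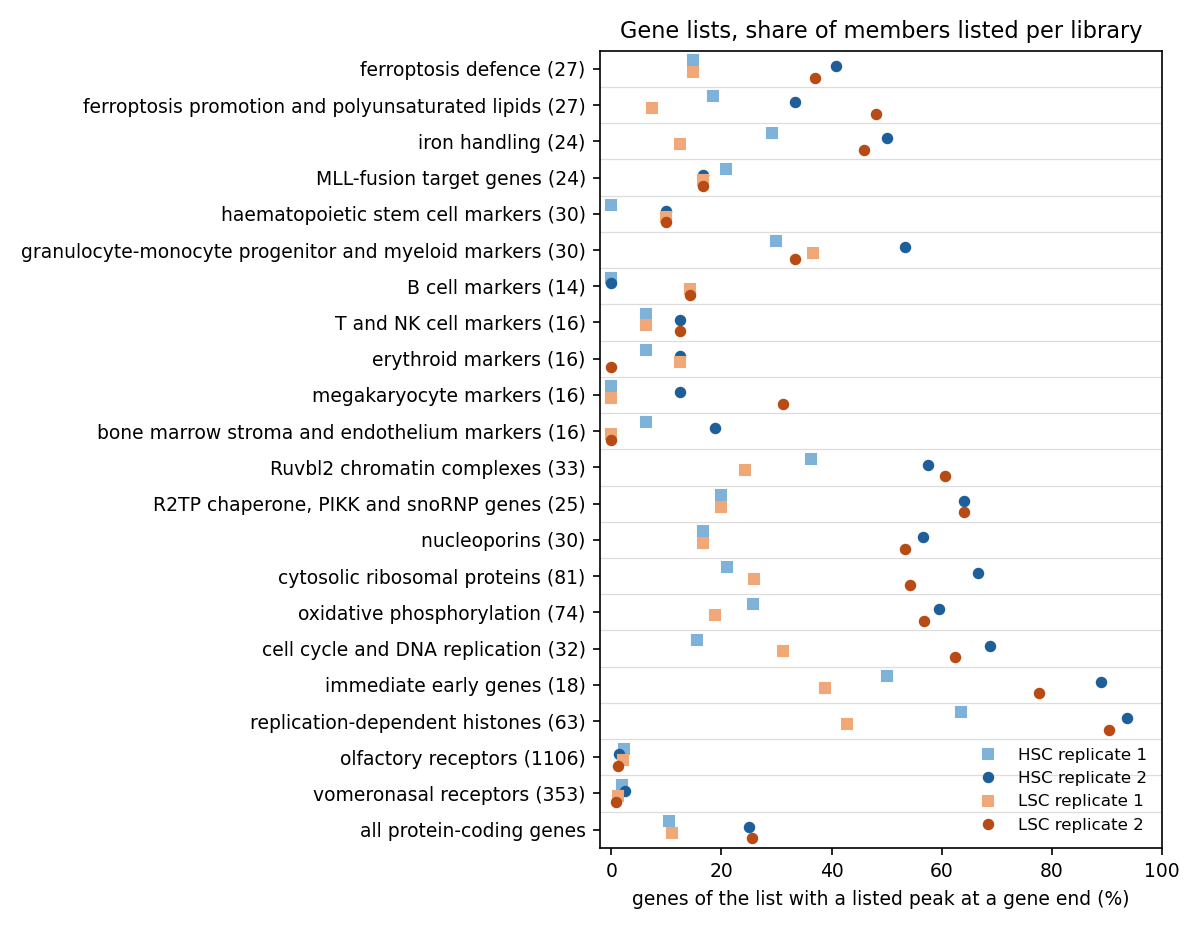
Share of the members of each gene list (list size in parentheses) with a listed peak at a gene end, in percent, for each of the 4 libraries, with all protein-coding genes in the bottom row. Squares are replicate 1 and circles replicate 2 libraries; in the replicate 2 libraries histone genes reached 93.7% in HSC and 90.5% in LSC, against 25.1% and 25.5% of all protein-coding genes.

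Genes that mark the blood lineages were compared next. Stem cell marker genes were listed in 0 of 30 cases (0%) in HSC replicate 1 and in 3 of 30 (10%) in each of the others, beside 10.6% and 25.1% of all protein-coding genes in HSC replicates 1 and 2 and 10.96% and 25.5% in LSC replicates 1 and 2. At its gene ends Hlf had no peak in any of the 4 deposited lists, and Procr, Hoxa9 and Meis1 had only peaks too weak to be listed. Granulocyte-monocyte and myeloid genes were listed in 9 and 16 of 30 cases in HSC replicates 1 and 2 and in 11 and 10 in LSC replicates 1 and 2, which was not tested against the other genes of each library. Spi1 (the transcription factor PU.1) and Ctsg (a granule protease) were listed in all 4 libraries. Mpo, the granule peroxidase, was listed in LSC replicate 1 alone, with peaks too weak to be listed in every other library. Of 24 genes that MLL fusions are known to target, 5, 4, 4 and 4 were listed, and Arid3a was listed in every library. B cell genes were listed in 0 of 14 cases in both HSC libraries and in 2 of 14 in each LSC library. T and NK cell genes gave 1, 2, 1 and 2 of 16, erythroid genes 1, 2, 2 and 0 of 16, megakaryocyte genes 0, 2, 0 and 5 of 16, and stroma and endothelium genes 1, 3, 0 and 0 of 16, in HSC replicates 1 and 2 and LSC replicates 1 and 2. Housekeeping groups moved mainly with the replicate number: ribosomal protein genes were listed in 17, 54, 21 and 44 of 81 cases, cell cycle and replication genes in 5, 22, 10 and 20 of 32, and genes of the R2TP chaperone, its kinase clients and snoRNPs in 5, 16, 5 and 16 of 25.

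The comparison the design is built on asked which sites differed between LSC and HSC. In LSC, 204 genes were listed in both libraries and in neither HSC library, and 26 of them had no peak of any strength at their ends in the HSC lists. The strongest of these 26 were Dut (dUTPase, which keeps uracil out of DNA), the adjacent Fbxl6 and Slc52a2 (a riboflavin transporter), Gtf2h1 (a TFIIH subunit), Chchd2 (a mitochondrial protein), Cdv3, Oas3 (an interferon-induced synthetase), Ik, Zfp457, Snx3, Shisa9, Rnf111, Hps5, Chst15 and Rlf. At Dut (chromosome 2, gene 125247248 to 125259049) the peak ranked 1035 in LSC replicate 1 and 1008 in LSC replicate 2, with folds of 94.1 and 49.6. Chchd2 (chromosome 5, gene 129881161 to 129887470) had folds of 68.6 and 55.9. In HSC, 191 genes were listed in both libraries and in neither LSC library, 21 of them with no LSC peak at their ends: Slc8b1 (a mitochondrial calcium exchanger), Btrc (an SCF ubiquitin ligase subunit), Hnrnpr, Smim8, Kdm3b (a histone demethylase), Rpl19, Aspdh, Bag5, Wfikkn2, Fam160b2, Exoc2, Itga1, Mrc2, Hspbap1 and Slc49a4 were the strongest. At Btrc (chromosome 19, gene 45363688 to 45533343) the folds were 42.4 and 18.2, and at Hnrnpr (chromosome 4, gene 136310942 to 136345981) 34.2 and 19.7. The best peaks of both libraries overlapped each other at 9 of the 15 named LSC genes, Dut and Chchd2 included, and at 6 of the 15 named HSC genes, while at Gtf2h1, Oas3 and Ik in LSC and at Slc8b1, Smim8, Rpl19 and Itga1 in HSC they lay at opposite ends of the gene.

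These counts did not stand out from those of pairs that mix the cell types. HSC replicate 1 with LSC replicate 2 gave 182 genes listed in exactly those libraries, and HSC replicate 2 with LSC replicate 1 gave 183. In the strict form these mixed pairs gave 7 and 31 genes, beside 26 for LSC and 21 for HSC. Strict counts are not on equal terms, because they depend on the full lists of the excluded libraries. Genes with any peak at an end numbered 8355 and 14122 in HSC replicates 1 and 2, and 10425 and 12878 in LSC replicates 1 and 2. The 4 libraries allow 3 splits into pairs, so the smallest two-sided p of an exact permutation test is 0.333 and no p under 0.05 can be reached. Among gene ends listed in 1 of the 2 libraries at each replicate number, the odds ratio for the same direction at both numbers was 1.17 (95% interval 0.871 to 1.57, p = 0.310, two-sided Fisher's exact test over genes), and it was 1.12 (0.827 to 1.53) with genes that share peaks counted once. Whether a gene list leaned to either cell type could not be decided: 16 of the 21 lists held 0 LSC-only and 0 HSC-only genes and the others 1 to 5. In the Fisher's exact test 0 lists passed and 0 had an unadjusted p under 0.05, but the smallest p that any list could have reached was 0.0257 before adjustment. List members listed in both libraries of one cell type and in neither of the other were Ing3, Rpl27a, Atp5pb and Ndufv2 in LSC, and Actr8, Nufip1, Rpl19, Ndufa6, Atp5j2, Atp5e and H4c12 in HSC. All of these but Rpl19 had weaker peaks in the other cell type. With a replicate left out the counts followed the weaker criteria: LSC-only genes numbered 821 without HSC replicate 2, 1799 without LSC replicate 1 and 818 without LSC replicate 2. HSC-only genes numbered 1671 without HSC replicate 1, 755 without HSC replicate 2 and 784 without LSC replicate 2. Olfactory receptor genes passed the list test without HSC replicate 2 and without LSC replicate 2, and histone genes without LSC replicate 2, where a lone replicate 1 library faced both libraries of the other cell type.

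**Figure D2:**
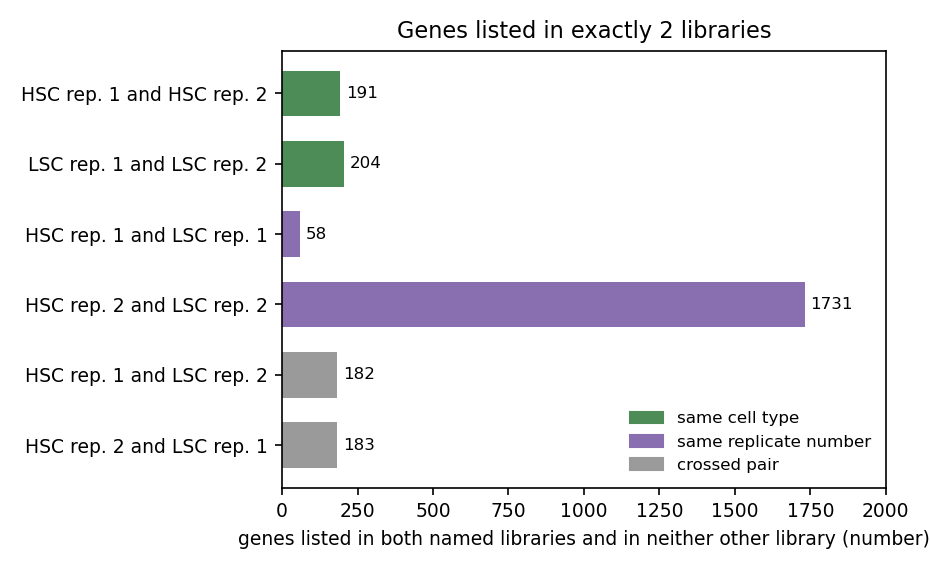
Number of protein-coding genes listed in exactly 2 of the 4 libraries, for each pair of libraries. Pairs of the same cell type (green, 191 and 204) lie near the crossed pairs (grey, 182 and 183), and the pair of replicate 2 libraries (purple) reaches 1731.

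Over the whole genome the picture was alike. Merging the listed peaks gave 68904 regions, of which 61674 (89.5%) were found in a single library and 789 in all 4. LSC-only regions numbered 454 and HSC-only regions 545, beside 495 and 539 for the crossed pairs. In the strict form they numbered 184 and 189, beside 150 and 226, and these counts too depend on the unequal full lists of the excluded libraries. The odds ratio for the same direction at both replicate numbers was 0.927 (0.776 to 1.11, p = 0.399, Fisher's exact test over regions). The strongest LSC-only regions without an HSC peak lay inside Lrp1b (chromosome 2, 41895887 to 41896283), at Dut, between genes on chromosome 6 (136979635 to 136980118, nearest to Pde6h), at Necap2 and at Chchd2. Their HSC counterparts lay inside Smg9, which takes part in nonsense-mediated decay (chromosome 7, 24399358 to 24399919), between genes on chromosome 11 (94988528 to 94990138, nearest to Ppp1r9b), at Zfp865, and inside Padi3 and Spred2.

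By overlap of listed peaks, the replicate 2 libraries resembled each other most and the replicate 1 libraries least of the 6 pairs. HSC replicate 2 and LSC replicate 2 shared 3577 listed genes, and 1731 genes were listed in both and in neither replicate 1 library, while HSC replicate 1 and LSC replicate 1 gave 58 such genes. The Jaccard index in base pairs was 0.134 for the replicate 2 pair and 0.0366 for the replicate 1 pair, beside 0.0495 for the HSC pair and 0.0466 for the LSC pair. The mean index within cell types minus that between them was −0.0190, near the −0.0178 of the crossed split. In both splits the replicate 2 pair fell among the pairs between groups, so the negative value is not a sign of a cell type effect. Within replicate numbers minus between them the index was 0.0368, which rests on the replicate 2 pair. The share of listed peaks at gene ends was 10.3% (95% Wilson interval 9.86 to 10.7) in HSC replicate 1 and 10.8% (10.3 to 11.2) in LSC replicate 1, and 24.9% (24.3 to 25.5) and 25.7% (25.1 to 26.3) in replicate 2 of HSC and LSC. Group means were 17.6% ± 10.4 in HSC and 18.2% ± 10.5 in LSC (SD, n = 2 each), and this spread follows the replicate number. Within each number the LSC share was the higher, with intervals that overlapped. LSC minus HSC means turned from 0.615 to −0.640 percentage points with peaks of a −log10 q of at least 20, and lay between −6.84 and 8.07 when 1 library was left out. Shifted peaks gave 3.62% to 4.26%. Over all deposited peaks the shares were closer, 5.69% and 6.71% in HSC replicates 1 and 2 and 5.88% and 7.77% in LSC replicates 1 and 2. Genes with any peak were 1.54 to 1.83 times as many as after shifts, against 2.91 to 6.53 times for listed peaks. Listed genes numbered 2311 and 5484 in HSC replicates 1 and 2 and 2399 and 5592 in LSC replicates 1 and 2, against 795 ± 33.8, 879 ± 41.2, 761 ± 27.6 and 856 ± 39.7 (SD over 100 shifts). The intervals cover counting error alone, since PCR copies are not independent molecules.

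**Figure D3:**
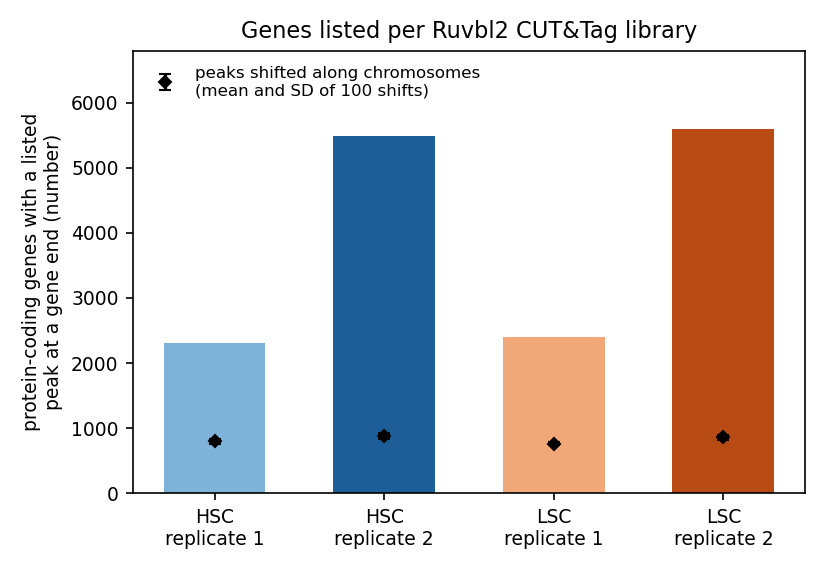
Number of protein-coding genes with a listed peak within 1000 bp of a gene end in each library (bars), with the mean and SD of 100 circular shifts of the same peaks (diamonds). The replicate 2 libraries reach 5484 and 5592 genes and the replicate 1 libraries 2311 and 2399, and shifted peaks give 761 to 879.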

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

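The tests of depth, of batch or sex, of repetition at both replicate numbers, of genes missed in replicate 1 and of rank shifts were chosen after the result was seen; those of the sex chromosomes and of narrow peaks were set beforehand. Signal outside the chromosomes compared flagged 2 items per library. The mitochondrial genome was covered by a single peak in each library, with a fold of 3734 in HSC replicate 1, 9006 in HSC replicate 2, 13615 in LSC replicate 1 and 15130 in LSC replicate 2. Peaks outside chromosomes 1 to 19, X and Y numbered 1813, 1133, 2099 and 1686 in the same order.

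The share of peaks at gene ends followed the replicate number: gene ends held 10.3% and 10.8% of listed peaks in the replicate 1 libraries and 24.9% and 25.7% in the replicate 2 libraries, a gap that narrowed to 5.69% and 5.88% against 6.71% and 7.77% over all deposited peaks. LSC replicate 1 showed no sign of lower depth, since its background pileup of 4.46 was slightly above that of both replicate 2 libraries (at most 4.34). That measure also reflects fragment length, and the handling of duplicate reads is unknown, so depth was not decided. For HSC replicate 1, with 2.66, depth cannot be told apart from other causes on 1 library. The gap did not rest on peaks on the sex chromosomes: on autosomes alone 1713 genes were listed in exactly the replicate 2 libraries, and at most 204 in a pair that does not share a number. This test could hardly have come out otherwise, since the X chromosome held at most 4.27% of the peaks of a library. Among what remains open are a library batch and the sex of the mice, both tied to the number. Peaks on the Y chromosome were at least 73.8 times as frequent in the replicate 1 as in the replicate 2 libraries. The shortest peaks were 224 and 180 bp against 291 and 281 bp. Duplicate fragments are open too: listed peaks under 1.1 times the shortest length numbered 2182 and 2548 in replicate 1 of HSC and LSC, and 461 and 615 in replicate 2. Among peaks at least 2 times the shortest length, 1675 genes were still listed in exactly the replicate 2 libraries. Batch and sex cannot be told apart from each other here, and the design names no biological difference between the replicate numbers.

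The shortest peaks of the replicate 1 libraries had a higher median fold (17.8 in HSC and 17.9 in LSC, for peaks under 1.1 times the shortest length) than those between 2 and 4 times that length (10.7 and 7.87), and lay at gene ends in 4.77% and 5.25% of cases. If they were stacks of duplicate fragments, other libraries would rarely hold them: the strong ones away from gene ends were overlapped 1.54 (HSC) and 1.55 (LSC) times as often as shifted positions, between the limits of 1.5 and 3 set beforehand. Peaks at least 4 times the shortest length reached 1.85 and 2.06 in the same libraries. For these wide peaks a ratio of 3 was out of reach or nearly so, because 35.1% (HSC) and 30.7% (LSC) of shifted positions were already overlapped. Against single libraries the wide peaks were overlapped 2.56 to 3.71 times and the narrow ones 1.57 to 1.85 times as often as shifted positions. Part of the narrow peaks may thus be duplicates, and these cannot be told apart from real sites. Whether binding that differs between cell types was the cause could not be decided. Overlap over chance with replicate 2 of the same cell type was 1.07 times (95% bootstrap interval 0.915 to 1.25) that with the other in LSC. In HSC it was 0.924 times (0.786 to 1.09). The overlapped peaks thus did not favour the same cell type. However, the limit of 1.5 was barely in reach, as overlap with the same cell type was itself 1.57 (HSC) and 1.69 (LSC) times chance. Only 27.1% (HSC) and 24.4% (LSC) of these peaks were overlapped by any other library.

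Genes listed in 1 cell type alone were about as many (204 and 191) as in the crossed pairs (182 and 183). A cell type difference that repeats at both replicate numbers may still exist, since the odds ratio of 1.17 had an interval up to 1.57. Of the 3577 genes listed in both replicate 2 libraries, HSC replicate 1 listed 34.4% and LSC replicate 1 listed 35.0%, and 66.5% and 77.3% had a peak of any strength there, but with fewer listed genes the replicate 1 libraries could have reached at most 64.6% and 67.1%, so whether missed genes account for the pattern was not decided. Over the 523 distinct peak sets behind genes listed in all 4 libraries, LSC minus HSC rank shifts at the 2 replicate numbers correlated with a Spearman rho of 0.0873 (95% bootstrap interval 0.00594 to 0.178, permutation p = 0.0460 over genes, which are not independent replicates; adjusted p = 0.0460 over 2 contrasts), a small positive correlation whose interval excludes 0. It lay below a limit of 0.1 set after it had been seen, and with 2 libraries per group a shared shift of this size remains open as a hypothesis.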

How the results depend on the processing

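The settings of −log10 q, peak length and replicate 2 alone, the all-4 list test and the odds ratios were chosen after the data were seen. Of 146 values under other settings, 77 counted as unmoved, 63 moved further, and 6 odds ratios crossed 1, none of which had passed its test. Unmoved meant within the spread, within 1.5 times the count reported, or, for odds ratios, on the same side of 1 with the same test outcome. The 77 overstate stability. They include the ranking by fold and the replicate block of both pairs, which could not differ. The spread for the gene-end share was 10.5 percentage points, so its changes of sign also counted as unmoved. Beyond list length and criteria, the cause was not tested. The values by setting were as follows. With the full lists, LSC-only and HSC-only regions numbered 13577 and 14828, LSC-only and HSC-only genes 826 and 744, genes in all 4 libraries 3413, lists past the all-4 test 12, the Jaccard index within minus between cell types −0.00422, and the odds ratio over regions 1.02. With the 10000 strongest peaks, the values were 223, 277, 134, 117 and 391, with 4 lists, the index −0.0271, and the odds ratios 0.956 over genes and 1.03 over regions. With the 40000 strongest, they were 1143 and 1205 regions, 314 LSC-only genes and an index of −0.0133. Overlap of at least 50% gave 208 and 330 regions and −0.0136, and summit windows an odds ratio over regions of 1.02. Gene-end windows of 3000 bp gave 368 LSC-only and 295 HSC-only genes, 1066 genes in all 4, 8 lists and an odds ratio of 0.989. A −log10 q of at least 20 gave 8755 and 5468 regions, 973 and 461 genes, 2471 genes in all 4, 13 lists, an index of −0.00629 and an odds ratio over genes of 0.995; peaks at least 2 times the shortest length gave an index of −0.0161. Of the 204 LSC-only and 191 HSC-only genes, 91 and 74 were also found with the 10000 strongest peaks, 130 and 118 with the 40000 strongest, 26 and 21 with the full lists, and 79 and 53 among the longer peaks. Among genes listed in exactly 2 libraries, the replicate 2 pair held the most under each setting of the list, overlap or window that was run. Leaving out 1 library at a time, which leaves 1 library in a group and no test between groups, gave an index between −0.0451 and 0.00652, LSC-only regions between 540 and 17318, HSC-only regions between 706 and 17354, LSC-only genes between 238 and 1799, HSC-only genes between 244 and 1671, genes in all libraries between 670 and 1253, 0 to 2 lists past the list test and 5 to 8 past the all-4 test. The replicate 2 libraries alone shared 3577 genes, with 11 lists past the all-4 test. A replicate block that required the difference at both numbers selected by construction the same 454 and 545 regions and 204 and 191 genes; the replicate 1 pair alone gave 18440 LSC-only and 18439 HSC-only regions and 1618 and 1530 genes, and the replicate 2 pair alone 15187 and 15226 regions and 2015 and 1907 genes. The deviations of same-numbered libraries from their group means correlated at 0.215 over genes, and peak names share a scheme within each number, but the labels do not say that a number marks a shared batch; the odds ratios and rank shifts set same-numbered libraries side by side without assuming so. Ranking by fold moved nothing, being the same order. A q under 0.001 removes no deposited peak and was replaced by the stricter −log10 q, and transcript starts were not run because the gene table used holds none. Depth is unknown, and a gene missing from a list of 20000 peaks is not shown to lack Ruvbl2.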

Other observations

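In the replicate 2 libraries, taken by themselves after the data were seen and with 1 library per cell type, 3577 of 21887 protein-coding genes were listed in both HSC and LSC. Histone genes were listed in both in 56 of 63 cases, immediate early genes in 13 of 18, cell cycle and replication genes in 18 of 32, genes of the R2TP chaperone, its kinase clients and snoRNPs in 13 of 25, ribosomal protein genes in 35 of 81, chromatin complex genes in 14 of 33, nucleoporin genes in 12 of 30, iron handling genes in 9 of 24, ferroptosis defence genes in 9 of 27, genes that promote ferroptosis in 7 of 27 and oxidative phosphorylation genes in 29 of 74. Stem cell marker genes were listed in both in 1 of 30 cases and MLL-fusion target genes in 3 of 24. Ribosomal protein genes were listed in HSC alone in 19 cases and in LSC alone in 9, and myeloid genes in 7 and 1. Vomeronasal receptors, a background list, leaned the same way with 8 and 2. Genes that promote ferroptosis leaned to LSC with 2 and 6. These lists were picked from 21 after the data were seen, and the differences have no replicate check. The replicate 1 libraries listed more ribosomal protein and myeloid genes in LSC (21 and 11) than in HSC (17 and 9).

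Wide peaks lay at gene ends more often than narrow ones in each library. Listed peaks at least 4 times as long as the library's shortest lay at gene ends in 45.1% of cases in HSC replicate 2 and 51.4% in LSC replicate 2, and in 21.8% and 20.0% in replicate 1 of HSC and LSC. Listed peaks under 1.1 times the shortest lay there in 13.2% and 12.4% of cases in the replicate 2 and 6.46% and 5.53% in the replicate 1 libraries. Over the 523 distinct peak sets behind genes listed in all 4 libraries, peak ranks of HSC replicate 2 and LSC replicate 2 correlated with a Spearman rho of 0.665 across genes, which are not independent replicates, and the other 5 pairs of libraries lay between 0.219 and 0.357. Over the same peak sets, rank shifts between the replicate numbers correlated between the cell types with a rho of 0.253 (permutation p = 1e-05, the smallest 100000 permutations can give; adjusted p = 2e-05).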
